A study of Homo sapiens with 6 samples.

How the data were processed

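The series holds 6 RNA-seq libraries from cells that the source and cell line labels name LNCaP, a human prostate cancer line, and the sample titles LNCaPE, and that the design text describes as a derivative resistant to enzalutamide, an antiandrogen drug. The labels put 3 libraries in the group shNC and 3 in the group shPDGFC, a stable short hairpin RNA (shRNA) knockdown of PDGFC. Per the labels' protocols, cells grew in DMEM with 10% fetal bovine serum, total RNA was extracted with Trizol, and single-end libraries were made with an Ion Total RNA-Seq kit. The labels speak of pooled RNA samples and do not say whether the 3 libraries of a group came from separate cultures. The p-values given here therefore measure only the spread between these libraries, which may be technical.

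The authors deposited a table of 60664 human Ensembl gene identifiers with a value per gene and library, and its header names no unit. The values were read as RPKM, reads scaled to gene length and to the library's total, from their own structure. Within each gene the deposited RPKM values of the 6 libraries stood in ratios of whole numbers after division by a factor per library, with a tolerance of 1e-12. This held for 37040 of the 37040 genes with any value. The whole reads behind each value were recovered from these steps, which gave library totals between 17360455 and 23930217 reads. Those recovered reads summed to between 99.45% and 99.46% of the totals, after 521 genes were rescaled by a common divisor. The aligner, the counting tool, the annotation and the strand setting are not given in the sources used here. The submitters' processing notes name the mouse builds GRCm38 and mm10, whereas all 60664 identifiers are human and 0 are mouse. Of 13109 genes compared, 414 had the union exon length of GENCODE version 29. Whether the other lengths differed through the annotation or through the definition of length was not tested. Coordinates are those of GENCODE version 29 on GRCh38, matched by Ensembl identifier, and 60463 identifiers received a symbol.

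The test planned before the data were examined assumed counts. Because the deposited values are RPKM, the fallback fixed at the same time became the main test. Genes with an RPKM of at least 1 in at least 3 libraries (15337 genes) were tested with limma 3.58.1 in R 4.3.3. The model compared shPDGFC with shNC on log2(RPKM + 1), with a mean-variance trend and no block. P-values were adjusted by the Benjamini-Hochberg method, and 0.05 was the threshold. Fold changes are on the log2(RPKM + 1) scale, which understates the change of genes with low RPKM. Levels are means ± SD over 3 libraries, and changes carry the standard error (SE) of the limma fit. A gene rose or fell only if its adjusted p was under 0.05.

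The gene lists, 31 in number, were written before the data were examined. Each was tested with camera in limma, which compares its members with all other tested genes, with a preset correlation of 0.01 and adjustment over the 30 lists with at least 5 tested members. The test was repeated with the correlation estimated from the data, and with fry, which asks whether the members of a list move one way on balance and compares them with no other genes. Counts of members that passed are given over all genes tested and adjusted over the list alone. The named genes followed a rule with 4 parts. They were the PDGF ligands and receptors, and the 12 genes with the largest rise and the 12 with the largest fall. The latter needed an adjusted p under 0.05, at least 5 CPM in the higher group, no overlap between the groups' libraries and an established symbol. Added to these were the 2 higher and the 2 lower members with the smallest p of each list, and the 3 most abundant members of 4 lists. Any other gene named was chosen after its values were seen. Some genes that the rule selects, and 1 list, are not reported here.

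The fitting procedure was tested on simulated reads for 15293 genes with 200 genes changed. It recovered 36% of the 50 genes changed 1.25-fold, 96% of those changed 1.5-fold, 94% of those changed 2-fold and 98% of those changed 4-fold, and called 12 unchanged genes. With no gene changed it made 1 call. The simulation used the same dispersion for every gene, drew genes independently and changed only genes with enough reads. Its 200 changed genes were also fewer than the 4571 called in the data, so these rates need not hold for the real libraries. A level of 3 reads, the floor used for genes at 0, was between 0.125 and 0.173 CPM per library. Such floors cover counting error only.

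Same-group libraries were compared before averaging. Their chi-square per degree of freedom lay between 1.462 and 2.566 over genes with at least 20 reads in a pair, above sampling noise, and no pair shared a value above 0. Between groups it lay between 7.085 and 9.974. No library was left out. Reads from genes that overlap on opposite strands cannot be told apart without the strand setting, and 51 of the 136 named genes have such an exon overlap in GENCODE version 29. Alternatives included other pseudocounts and filters, each library left out in turn, the replicate number as a block, a stricter threshold and the other list tests. Further alternatives, chosen after seeing the data, were median-ratio and upper-quartile scaling, limma-voom on the recovered reads, removal of GC content or length trends, and limma treat at 1.5-fold. Transcript GC content was known for 15232 of 15337 tested genes (99.3%). Tables and plots were made with Python 3.11.15, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.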

Results

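RNA-seq was used to compare cells labelled LNCaP (LNCaPE in the sample titles) that carried a hairpin against PDGFC (shPDGFC, n = 3) with cells that carried the hairpin labelled shNC (n = 3). PDGFC encodes platelet-derived growth factor C, a secreted ligand of PDGF receptors. The series asks whether this ligand acts on the cells that make it, through the small GTPase RAP1 and the MAPK cascade, in enzalutamide resistance. The shNC libraries held 23930217, 18258988 and 22959212 reads and the shPDGFC libraries 17360455, 20905911 and 20115873 reads. Between 14996 and 15400 genes per library reached an RPKM of 1.

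PDGFC mRNA was lower in every shPDGFC library than in any shNC library. Its level was 8.35 ± 0.32 RPKM (SD, n = 3) in shNC and 2.65 ± 0.31 RPKM (SD, n = 3) in shPDGFC, 0.318 times the shNC level. Per library it was 8.19, 8.71 and 8.13 RPKM in shNC against 3.0, 2.43 and 2.52 RPKM in shPDGFC. The gene (ENSG00000145431, GRCh38 chromosome 4, 156760454 to 156971394) fell by 1.36 ± 0.066 (SE) on the log2 scale (limma, adjusted p = 0.00016), on 2476 reads in shNC and 702 in shPDGFC.

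Of the other PDGF genes, NRP1, a co-receptor, rose from 10.5 ± 0.23 to 12.4 ± 0.36 RPKM (SD, n = 3; adjusted p = 0.0035). The ligands PDGFA (1.67 and 2.09 RPKM in shNC and shPDGFC) and PDGFD (3.18 and 2.69 RPKM) did not pass the test (adjusted p = 0.093 and 0.096). The receptor PDGFRA was measured at 0.969 ± 0.061 and 1.05 ± 0.099 RPKM (SD, n = 3; adjusted p = 0.62), and PDGFRL at 4.21 and 4.38 RPKM (adjusted p = 0.53). PDGFRB (0.404 and 0.329 RPKM) and PDGFB (0.302 and 0.370 RPKM) lay below the level tested. Over this list 1 gene rose and 1 fell of 6 tested, also when adjusted over the list alone, and camera gave an adjusted p of 0.93. The list's median log2 change was 0.05 (0.023 to 0.11 under the alternatives) and its mean -0.17, set by PDGFC. PDGFD passed when shPDGFC replicate 2 was left out (adjusted p = 0.035).

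Across the transcriptome, 2173 genes were higher and 2398 lower in shPDGFC among 15337 tested. Most changes were small. Of the higher genes 2132 changed less than 1.5-fold, as did 2327 of the lower genes, and 12 genes changed at least 2-fold (5 higher, 7 lower). The groups did not overlap in 46.8% of tested genes, where chance gives 10%. The share of reads from mitochondrial genes was 3.75%, 4.08% and 3.88% in shNC and 4.20%, 4.68% and 4.20% in shPDGFC, without overlap between the groups. The count of 2-fold genes depended on the pseudocount and filter, from 3 to 61, and was 68 with limma-voom on the recovered reads.

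Transcripts that ERK signalling is known to induce, including its own feedback inhibitors, were higher in shPDGFC. Of 25 tested members of this list 19 rose and 1 fell, also when adjusted over the list alone, with a median log2 change of 0.39. ETV5 rose from 1.29 ± 0.22 to 3.43 ± 0.21 RPKM and ETV4 from 3.10 ± 0.34 to 6.52 ± 0.42 RPKM (SD, n = 3). These encode ETS transcription factors. SPRY4, which restrains receptor tyrosine kinase signalling, rose from 0.526 ± 0.14 to 1.93 ± 0.25 RPKM, and DUSP6, an ERK phosphatase, from 1.39 ± 0.14 to 2.86 ± 0.24 RPKM (SD, n = 3). CCND1, the gene for cyclin D1, rose from 31.9 ± 0.60 to 37.5 ± 0.36 RPKM (SD, n = 3).

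The member that fell was MYC, from 32.8 ± 0.29 to 26.0 ± 0.86 RPKM (SD, n = 3; limma, adjusted p = 0.00074). HMGA2 was measured at 35.7 and 35.5 RPKM (adjusted p = 0.81). Further members that rose, chosen after their values were seen, were DUSP4, DUSP5, SPRY2, SPRED2, ETV1, EGR1, FOS, FOSL1, EPHA2 and HBEGF. The list's rise relative to other genes passed camera (adjusted p = 1.3e-08), with an adjusted p = 0.048 with an estimated correlation. ETV4 shares exon sequence with DHX8 on the opposite strand (29.7 RPKM, log2 change -0.069, adjusted p = 0.092).

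**Figure D1:**
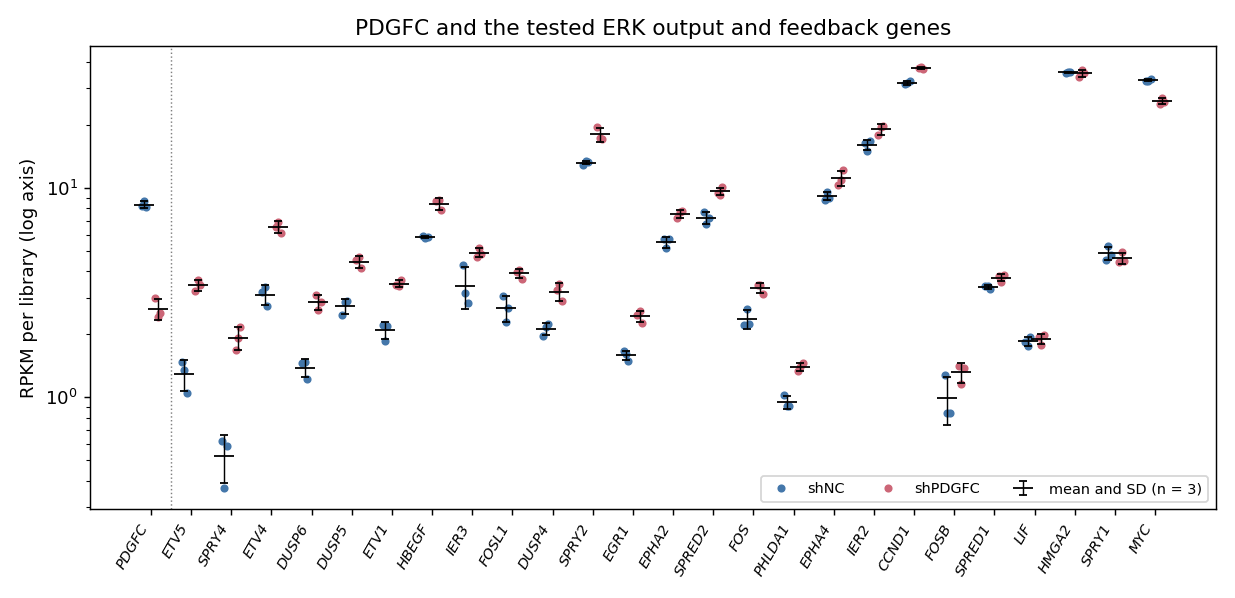
RPKM per library on a log axis for PDGFC (left of the dotted line) and the 25 tested ERK output and feedback genes, ordered by log2 change; points are libraries, horizontal marks means and bars SD (n = 3 per group). PDGFC lay between 8.13 and 8.71 RPKM in shNC and between 2.43 and 3.0 RPKM in shPDGFC, while 19 of the 25 listed genes were higher and MYC was lower in shPDGFC.

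The genes that encode the ERK cascade itself went both ways. Of 27 tested, 7 rose and 5 fell (8 and 5 when adjusted over the list alone). NF1, a negative regulator of RAS, fell from 17.1 ± 0.26 to 11.9 ± 0.58 RPKM (SD, n = 3), and MAP2K1, which encodes the kinase MEK1, from 34.3 ± 1.0 to 27.7 ± 1.4 RPKM. PEBP1, an inhibitor of RAF, rose from 117.0 ± 1.4 to 131.5 ± 1.1 RPKM (SD, n = 3). The list did not stand apart from other genes (camera, adjusted p = 0.90), and its median of -0.0044 and camera's upward direction differed in sign. MAP2K1 overlaps SNAPC5 on the opposite strand, which also fell (log2 change -0.192, adjusted p = 0.021).

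RAP1 signalling components showed no common direction. Of 32 tested, 5 rose and 4 fell, also when adjusted over the list alone, with a median log2 change of 0.02 (0.0093 to 0.04 under the alternatives). The adaptor CRK rose from 27.2 ± 0.46 to 32.9 ± 1.1 RPKM (SD, n = 3), as did RAPGEF2, an exchange factor for RAP1 (11.8 to 13.8 RPKM), and RAP1B (11.3 to 12.9 RPKM). RAPGEF5 fell from 5.37 ± 0.32 to 4.37 ± 0.16 RPKM, and the scaffold gene MAGI2 from 2.22 to 1.70 RPKM. AFDN (30.7 and 30.1 RPKM) and CRKL (37.3 and 37.4 RPKM) did not pass (adjusted p = 0.50 and 0.89). The list did not pass camera (adjusted p = 0.58). MAGI2 shares exon sequence with the abundant MAGI2-AS3 on the opposite strand (84.7 RPKM), so the fall of MAGI2 is uncertain. MAGI2-AS3 itself did not pass (log2 change -0.056, adjusted p = 0.25). The call for MAGI2 was also lost without shNC replicate 1 (adjusted p = 0.069), shNC replicate 2 (0.056), shPDGFC replicate 2 (0.054) or shPDGFC replicate 3 (0.059).

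Among genes with at least 5 CPM, no overlap between groups and an established symbol, the largest rise on the log2(RPKM + 1) scale was that of ANXA1, which encodes the calcium-dependent membrane-binding protein annexin A1 (chromosome 9, 73151757 to 73170393). It went from 23.1 ± 0.83 to 52.5 ± 2.1 RPKM (SD, n = 3), a log2 change of 1.15 ± 0.038 (SE; adjusted p = 5.4e-05). ANKRD1 rose from 10.0 ± 0.81 to 20.8 ± 0.93 RPKM (chromosome 10, 90912096 to 90921276). CGA, the common alpha subunit of glycoprotein hormones, rose from 9.51 ± 0.51 to 18.3 ± 1.5 RPKM, and EMILIN2, an extracellular matrix gene, from 2.13 ± 0.055 to 4.24 ± 0.25 RPKM (SD, n = 3). The noncoding MIR503HG rose from 19.7 to 33.5 RPKM. TENM1 (0.349 to 1.5 RPKM) and ACTBL2 (0.661 to 1.83 RPKM) rose from low levels, and by ratio TENM1, SPRY4, ACTBL2 and ETV5 rose more than ANXA1. TENM1 shares exon sequence with the abundant STAG2 on the opposite strand (69.0 RPKM), so its level is uncertain. STAG2 fell (log2 change -0.091, adjusted p = 0.024), which argues against reads from STAG2 as the source of TENM1's rise. ACTBL2 has close actin paralogs, so its rise is uncertain.

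Under the same limits and on the same scale, the largest falls beside PDGFC were those of FAM133A, from 4.40 ± 0.37 to 1.14 ± 0.065 RPKM (SD, n = 3; log2 change -1.34 ± 0.069 SE, adjusted p = 0.00020), and NRN1, the gene for neuritin, from 55.7 ± 1.8 to 30.2 ± 0.59 RPKM. IDH3A, a subunit of the mitochondrial isocitrate dehydrogenase, fell from 22.9 ± 0.41 to 12.3 ± 0.33 RPKM, and SERPINH1, a collagen chaperone, from 55.8 ± 1.6 to 32.6 ± 1.1 RPKM (SD, n = 3). LIPA, the lysosomal acid lipase, fell from 37.7 to 22.0 RPKM and CHRDL1, a secreted BMP antagonist, from 33.4 to 20.02 RPKM. PKIA, an inhibitor of protein kinase A, fell from 8.10 to 4.31 RPKM. FAM171A1 (13.3 to 7.65 RPKM), TC2N (8.18 to 4.56 RPKM), ABHD1 (4.90 to 2.41 RPKM) and ZNF93 (2.51 to 1.12 RPKM) complete the 12. ABHD1 overlaps PREB and IDH3A overlaps CIB2 on the opposite strand, and FAM133A and ZNF93 have close paralogs.

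The listed autophagy and lysosome genes rose as a group. Of 35 tested, 23 rose and 2 fell (26 and 2 when adjusted over the list alone), with a median log2 change of 0.17. CTSA, a lysosomal carboxypeptidase, rose from 28.6 ± 0.61 to 38.7 ± 0.19 RPKM, and PSAP, the precursor of the saposins, from 118.8 ± 1.1 to 155.5 ± 2.5 RPKM (SD, n = 3). The members that fell were TFEB, a transcription factor for lysosomal genes (2.28 to 1.80 RPKM), and GLA (252.5 to 238.7 RPKM). LIPA, the lysosomal acid lipase given above, is not in the list and fell by more than CTSA or PSAP rose (log2 change -0.75). Camera gave an adjusted p of 1.1e-10 and an adjusted p = 0.048 with an estimated correlation. TFEB lost its call without any of the 6 libraries (adjusted p between 0.052 and 0.094), and GLA without any except shNC replicate 2 (between 0.072 and 0.12).

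Targets of the YAP and TEAD transcription factors were also higher. Of 21 tested, 13 rose and 1 fell (14 and 1 when adjusted over the list alone), with a median log2 change of 0.16. CCN1 rose from 6.14 ± 0.42 to 9.86 ± 0.30 RPKM and CCN2 from 1.53 ± 0.10 to 3.10 ± 0.15 RPKM (SD, n = 3). These encode matricellular proteins, and ANKRD1, given above, is in this list too. AMOTL1, an angiomotin family gene, fell from 20.7 ± 0.20 to 17.8 ± 0.48 RPKM. The list passed camera (adjusted p = 4.0e-05), but an adjusted p = 0.075 with an estimated correlation.

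Cytosolic ribosomal protein mRNAs were lower. Of 73 tested, 37 fell and 0 rose (43 and 0 when adjusted over the list alone), with a median log2 change of -0.15. RPL4 fell from 499.8 ± 0.99 to 394.1 ± 5.1 RPKM and RPL19 from 1186 ± 12.3 to 952.2 ± 21.6 RPKM (SD, n = 3). Camera gave an adjusted p of 1.4e-10, but an adjusted p = 0.50 with an estimated correlation, since the members varied together within groups (estimated correlation 0.31). Reads of these genes can be shared with their many processed pseudogenes.

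Other growth and energy genes did not stand apart as lists. Of 30 nucleolar MYC targets 5 rose, among them MYBBP1A (20.6 to 24.8 RPKM) and RRP9 (14.4 to 16.9 RPKM), and NPM1 fell (1081 to 976.2 RPKM; camera, adjusted p = 0.46). Adjusted over the list alone, 4 rose and 1 fell. Of 42 nuclear-encoded oxidative phosphorylation genes 4 rose and 4 fell (3 and 2 when adjusted over the list alone; camera, adjusted p = 0.93). SDHB, a subunit of complex II, rose from 85.2 ± 2.3 to 103.0 ± 1.2 RPKM (SD, n = 3), and CYC1 from 52.98 to 57.5 RPKM. ATP5PB fell from 90.2 to 81.7 RPKM. NDUFV2 fell from 1.63 to 0.996 RPKM on few reads, 92 in shNC and 50 in shPDGFC, so its level is uncertain. Of 13 mitochondrially encoded mRNAs 3 rose and 1 fell (4 and 1 when adjusted over the list alone), with a median log2 change of 0.20 and a camera adjusted p of 0.071. MT-CYB rose from 1698 ± 67.7 to 2072 ± 153.9 RPKM and MT-ND5 from 1910 ± 188.8 to 2407 ± 216.8 RPKM (SD, n = 3). MT-ND6, encoded on the other strand of the mitochondrial genome, fell from 211.4 ± 11.7 to 164.2 ± 8.9 RPKM. The mitochondrial list passed under 7 alternatives, among them without shNC replicate 2 (adjusted p = 0.031), shPDGFC replicate 1 (0.043) or shPDGFC replicate 3 (0.032). It did not pass with an estimated correlation of 0.55 (adjusted p = 0.65), and without shPDGFC replicate 2 its median was 0.12 (adjusted p = 0.23). MT-CYB lost its call without shNC replicate 1 (adjusted p = 0.052), MT-ND5 without shNC replicate 1 or 3 or shPDGFC replicate 2 or 3 (0.053 to 0.081), and NPM1 without shNC replicate 1 or 3 or shPDGFC replicate 3 (0.072 to 0.079).

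Most androgen-induced transcripts that changed were lower in shPDGFC. Of the listed androgen-induced targets, 37 were in the table and 24 were tested, of which 1 rose and 7 fell (2 and 7 when adjusted over the list alone), with a median log2 change of -0.05. FKBP5, a co-chaperone of steroid receptors, fell from 44.0 ± 1.5 to 35.9 ± 1.0 RPKM and HOMER2 from 33.7 ± 0.70 to 28.5 ± 0.46 RPKM (SD, n = 3). CENPN, the member that rose, went from 19.0 to 20.9 RPKM. MED28 (12.5 and 12.2 RPKM) did not pass (adjusted p = 0.65). Camera gave an adjusted p of 0.32 for the list, while fry gave 0.023. The call for CENPN was lost without shNC replicate 2 (adjusted p = 0.071), shNC replicate 3 (0.059), shPDGFC replicate 1 (0.068) or shPDGFC replicate 3 (0.073).

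Several prostate androgen targets were at or near 0 in all 6 libraries. Of the 37, 10 lay under 0.2 RPKM in every library. Beside these, 24 of the 37 reached 1 RPKM in every library. In 10000 random lists of as many protein-coding genes the median was 22, and 33.3% had at least 24. That comparison takes no account of how many of the 37 are expressed in LNCaP. It therefore cannot decide whether the list was short of expressed genes for such cells. KLK3, the gene for prostate-specific antigen, had 1 read over the 3 shNC libraries and 0 over the 3 shPDGFC libraries, which allows up to 0.173 CPM in the shallowest library. KLK2 also had 1 and 0 reads, and STEAP4 0 and 0. TMPRSS2 was at 0.628 ± 0.062 and 0.449 ± 0.13 RPKM (SD, n = 3). FOXA1 (7.26 and 6.91 RPKM) and HOXB13 (8.71 and 8.62 RPKM) were expressed. These genes were named after their values were seen.

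Of 8 tested androgen-repressed genes, SESN3 rose (11.7 to 13.4 RPKM) and PRUNE2 (1.84 to 1.21 RPKM) and PCDHB2 (1.45 to 0.994 RPKM) fell, also when adjusted over the list alone (camera, adjusted p = 0.58). Fry gave 0.0015 for this list, with a median log2 change of -0.08, so both androgen lists were downward by fry. PRUNE2 overlaps GCNT1 on the opposite strand, which also fell (log2 change -0.307, adjusted p = 0.0038). PCDHB2 lost its call without shNC replicate 1 or 3 or shPDGFC replicate 1 or 3 (adjusted p between 0.060 and 0.086).

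**Figure D2:**
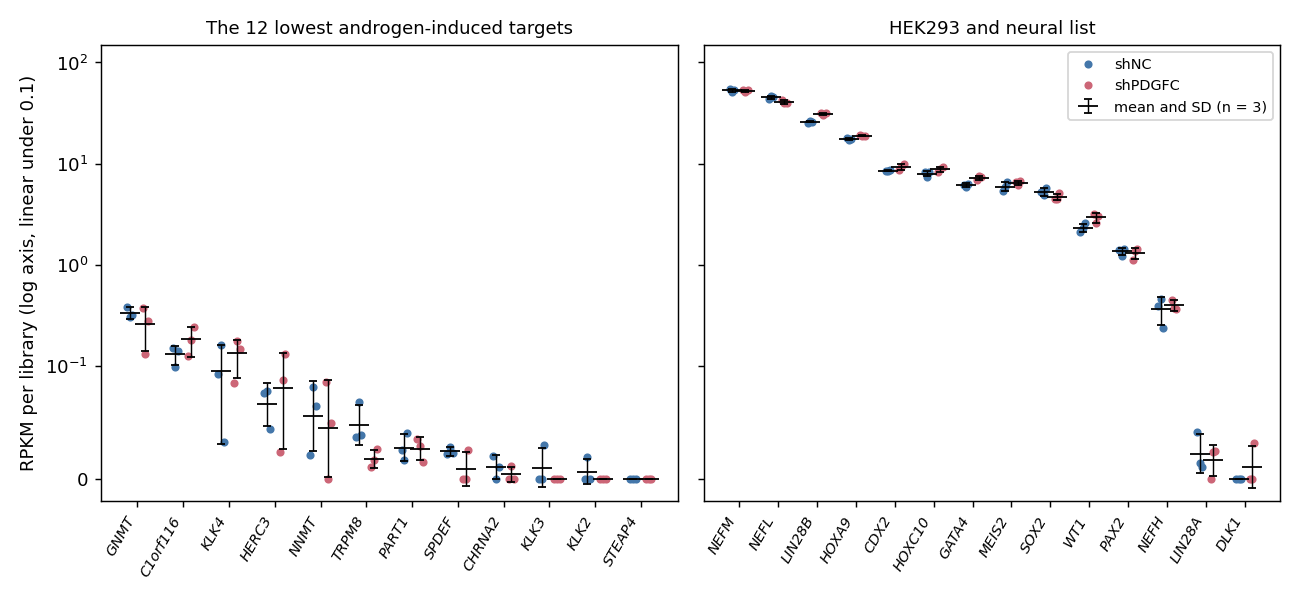
RPKM per library (log axis, linear under 0.1) for the 12 androgen-induced targets with the lowest shNC mean (left) and for the 14 genes of the HEK293 and neural list (right); points are libraries, marks means and bars SD (n = 3 per group). KLK3, KLK2 and STEAP4 lie at or next to 0 in both groups, while NEFM lies near 53 RPKM and LIN28B at 25.9 RPKM in shNC and 31.2 RPKM in shPDGFC.

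Cell cycle genes went both ways. Of 45 E2F targets and replication genes 6 rose and 9 fell (7 and 9 when adjusted over the list alone; camera, adjusted p = 0.52). MCM2, of the replicative helicase, rose from 83.6 to 93.0 RPKM and RFC4, overlapped by EIF4A2 on the opposite strand (183.4 RPKM), from 65.9 to 76.3 RPKM, whereas CDC6 fell from 64.1 to 55.9 RPKM and DTL from 65.5 to 58.6 RPKM. Of 37 G2/M and mitosis genes 11 rose and 2 fell (11 and 3 when adjusted over the list alone), with a median log2 change of 0.05. CCNB1, the gene for cyclin B1, rose from 80.3 ± 2.4 to 98.3 ± 1.9 RPKM and ANLN from 43.7 to 50.7 RPKM, but TOP2A, topoisomerase II alpha, fell from 231.5 ± 3.9 to 164.3 ± 1.6 RPKM (SD, n = 3) and CKAP2L from 18.8 to 16.8 RPKM. Camera gave an adjusted p of 0.040 for G2/M and 0.50 with an estimated correlation. The G2/M call was also lost without shNC replicate 1 (adjusted p = 0.087), shNC replicate 3 (0.062) or shPDGFC replicate 1 (0.066, with the median at 0.0245), and with either stricter filter, upper-quartile scaling or the length correction (0.052 to 0.12).

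Replication-dependent histone genes, whose near-identical copies share reads, rose in 4 of 12 tested and fell in 0, also when adjusted over the list alone. H2AC6 rose from 14.4 ± 1.1 to 20.95 ± 1.5 RPKM and H2BC21 from 4.87 ± 0.13 to 6.01 ± 0.26 RPKM (SD, n = 3). Camera gave an adjusted p of 0.012, but an adjusted p = 0.30 with an estimated correlation and 0.060 with limma-voom. Of 25 p53 targets 4 rose and 10 fell (5 and 10 when adjusted over the list alone; camera, adjusted p = 0.24). PMAIP1, which encodes the BH3-only protein NOXA, rose from 103.4 ± 1.6 to 132.5 ± 6.9 RPKM and CDKN1A, the gene for p21, from 27.9 to 32.7 RPKM. BTG2 fell from 18.4 ± 1.1 to 12.2 ± 0.76 RPKM and DDB2 from 16.3 to 13.6 RPKM.

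Metabolic genes moved in both directions. Of 24 cholesterol synthesis genes 2 rose and 9 fell (3 and 10 when adjusted over the list alone; camera, adjusted p = 0.29). INSIG1, a sterol-regulated brake on SREBP processing, fell from 22.5 ± 0.79 to 14.5 ± 0.22 RPKM (SD, n = 3) and SREBF2 from 18.9 to 16.4 RPKM, while IDI1 rose from 33.1 to 40.8 RPKM and SC5D from 25.1 to 29.2 RPKM. Of 21 fatty acid synthesis genes 1 rose and 7 fell, also when adjusted over the list alone (camera, adjusted p = 0.51), among them SCD (64.7 to 55.0 RPKM) and ACACA (24.5 to 21.8 RPKM). ELOVL1, the gene that rose (26.2 to 29.6 RPKM), lost its call without shNC replicate 1 or 3 or shPDGFC replicate 1 or 3 (adjusted p between 0.055 and 0.097). Of 32 glycolysis and hypoxia genes 6 rose and 12 fell (6 and 14 when adjusted over the list alone), with a camera adjusted p of 0.071. This became 0.042 without shNC replicate 2, 0.15 without shNC replicate 3, 0.16 without shPDGFC replicate 2 and 0.51 with an estimated correlation. The glucose transporter SLC2A3 rose from 28.4 ± 0.70 to 40.0 ± 0.75 RPKM (SD, n = 3) and PFKP from 40.5 to 47.3 RPKM, while HK2 (19.7 to 16.5 RPKM) and PDK1 (8.09 to 6.68 RPKM) fell. HK2 overlaps AC019069.1 on the opposite strand, which also fell (log2 change -0.246, adjusted p = 0.0099).

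Stress and inflammatory genes moved in both directions. Of 32 ATF4 and unfolded protein response genes 11 rose and 3 fell (12 and 5 when adjusted over the list alone; camera, adjusted p = 0.11). ATF3 rose from 48.2 to 53.7 RPKM and SLC7A5 from 21.8 to 24.3 RPKM, and DDIT4, an mTORC1 inhibitor, fell from 59.0 ± 3.1 to 42.3 ± 1.4 RPKM (SD, n = 3) and CEBPG from 40.3 to 36.2 RPKM. Of 27 type I interferon response genes 5 rose, among them IFI6 (12.6 to 15.2 RPKM) and HERC5 (8.67 to 10.1 RPKM), and IFIT5 fell from 9.62 to 8.01 RPKM (4 and 1 when adjusted over the list alone; camera, adjusted p = 0.28). Of 9 NF-kB response genes 3 rose and 1 fell, also when adjusted over the list alone (camera, adjusted p = 0.32). TNFAIP3 rose from 1.47 to 2.16 RPKM and NFKB1 from 5.87 to 7.23 RPKM, while TRAF1 fell from 2.16 to 1.42 RPKM, a call lost without shNC replicate 1 (adjusted p = 0.052).

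Among 25 FOXO and PI3K-AKT feedback genes 6 rose and 7 fell (7 and 8 when adjusted over the list alone; camera, adjusted p = 0.93, upward against a median of -0.03). AKT1 rose from 46.6 ± 1.4 to 54.0 ± 0.48 RPKM (SD, n = 3). KLF6 rose from 9.14 to 12.3 RPKM and PIK3CB, a catalytic subunit of PI3K, fell from 8.71 to 6.02 RPKM.

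The 3 lists of cell state markers did not stand apart from other genes in camera, while fry called the epithelial (adjusted p = 0.023) and mesenchymal (0.011) lists upward and the neuroendocrine list downward (0.038). Of 14 epithelial genes 5 rose and 2 fell (6 and 3 when adjusted over the list alone; camera, adjusted p = 0.28). KRT18, overlapped by KRT8 on the opposite strand (83.7 RPKM), rose from 60.7 ± 0.63 to 77.2 ± 4.2 RPKM and OCLN from 5.04 to 6.44 RPKM, whereas CDH1, the gene for E-cadherin, fell from 1.37 ± 0.18 to 0.789 ± 0.089 RPKM (SD, n = 3) and EPCAM from 10.4 to 8.61 RPKM. Of 26 mesenchymal and matrix genes 9 rose and 5 fell (10 and 6 when adjusted over the list alone; camera, adjusted p = 0.23). VIM, the gene for vimentin, rose from 270.4 ± 3.9 to 332.6 ± 7.5 RPKM and CDH2, the gene for N-cadherin, from 41.5 to 47.7 RPKM. ACTA2 fell from 9.16 to 7.10 RPKM and COL5A1 from 3.37 to 2.51 RPKM. ACTA2 overlaps FAS on the opposite strand, which also fell (log2 change -0.266, adjusted p = 0.020). Of 16 neuroendocrine markers CHGA rose (1.61 to 2.13 RPKM), and ONECUT2 (6.79 to 4.73 RPKM), POU3F2 (9.41 to 7.82 RPKM) and 1 further gene fell (2 and 6 when adjusted over the list alone; camera, adjusted p = 0.52). EPCAM lost its call without shNC replicate 1 or 2 or shPDGFC replicate 2 or 3 (adjusted p between 0.074 and 0.080), and CHGA without shNC replicate 1 or 2 or shPDGFC replicate 1 or 2 (0.055 to 0.066).

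Markers of other cells were examined as well. Of 13 tested genes of other prostate lines and basal epithelium 5 rose and 3 fell (6 and 3 when adjusted over the list alone; camera, adjusted p = 0.071). The list passed upward with either stricter filter (adjusted p = 0.029 in both), limma-voom (0.032) and fry (0.00012), but not with an estimated correlation (0.41). ANXA1 is in this list, ANXA2 rose from 98.7 to 118.2 RPKM, and S100A2 (3.43 to 2.51 RPKM) and ITGA3 (4.10 to 3.40 RPKM) fell. Of 5 tested fibroblast genes FBLN1 (23.7 to 27.4 RPKM) and COL3A1 (0.883 to 1.46 RPKM) rose and LUM fell (11.3 to 7.96 RPKM; 2 and 2 when adjusted over the list alone; camera, adjusted p = 0.90). Of 11 tested genes of the list for HEK293, a human embryonic kidney line with neural transcripts, 3 rose, among them LIN28B (25.9 to 31.2 RPKM) and GATA4 (6.13 to 7.27 RPKM). NEFL, of the same list, fell from 45.1 to 40.9 RPKM (4 and 1 when adjusted over the list alone; camera, adjusted p = 0.16). Of 12 leukocyte genes 3 were tested, too few for a list test, and HLA-DRA fell from 10.0 to 6.88 RPKM while 0 rose, also when adjusted over the list alone. GATA4 lost its call without shPDGFC replicate 3 (adjusted p = 0.053) and NEFL without shNC replicate 2 or 3 or shPDGFC replicate 2 or 3 (0.085 to 0.094).

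**Figure D3:**
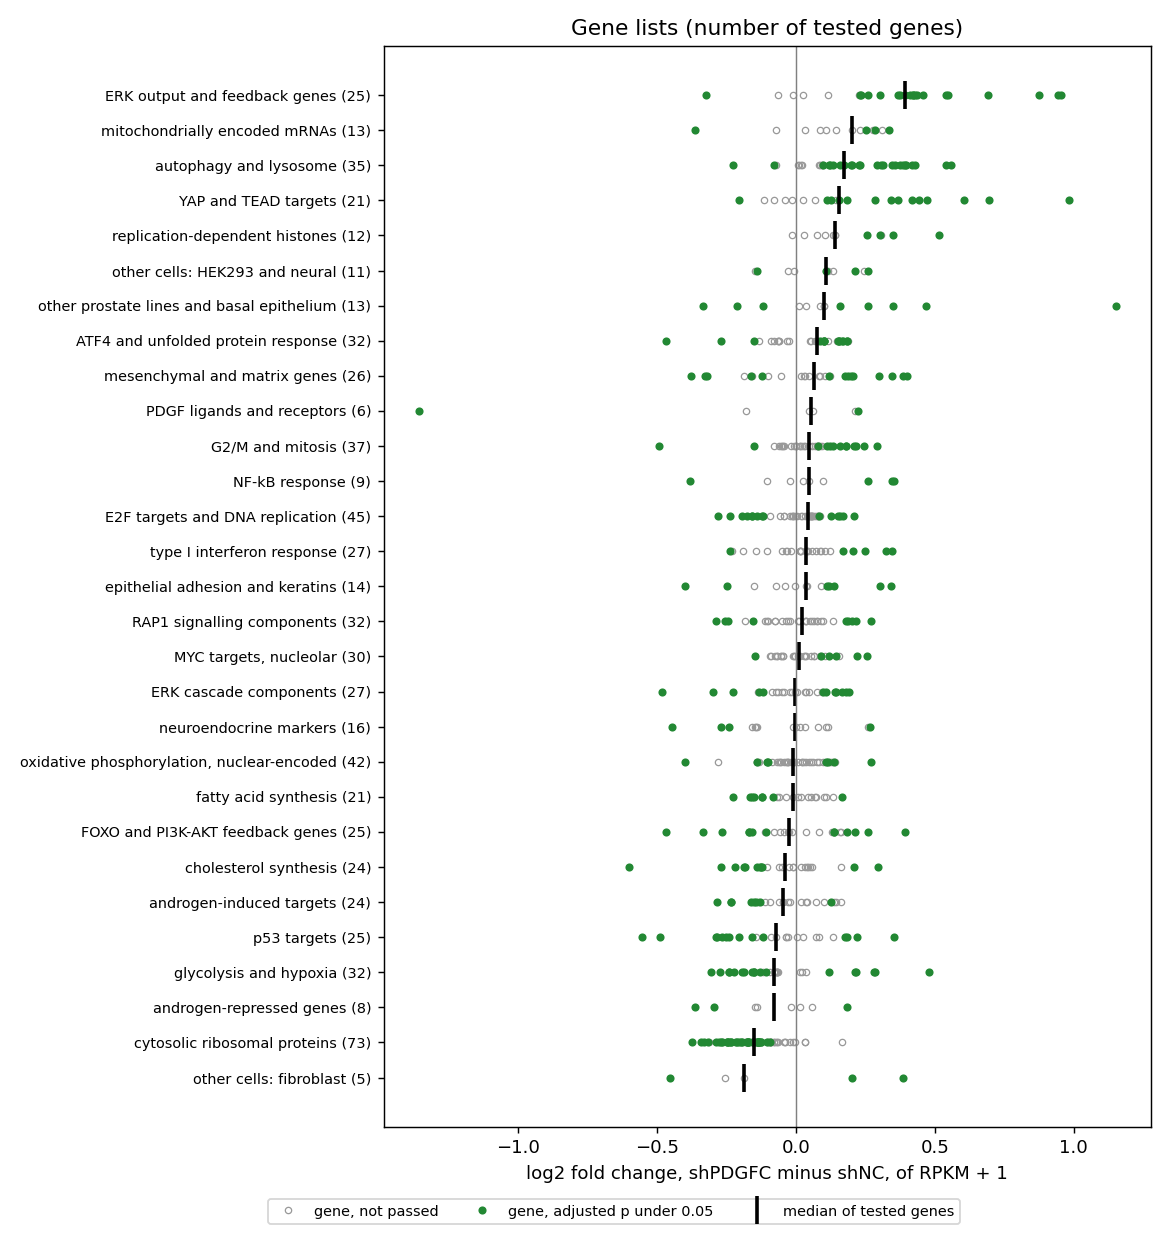
Log2 fold change of RPKM + 1, shPDGFC minus shNC, for each tested gene of 29 lists with at least 5 tested genes, whose numbers stand in brackets; filled points passed at an adjusted p under 0.05, open points did not, and bars mark each list's median. ERK output and feedback genes have the highest median, 0.39, and ribosomal proteins have a median of -0.15 with 37 of 73 genes lower.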

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

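Median-ratio and upper-quartile scaling, limma-voom, the GC and length corrections and limma treat were chosen after seeing the data. Fits that need a count model, intended at the start (edgeR with other scaling factors and glmTreat, DESeq2, limma-voom with TMM) were not run, and limma-voom on the recovered reads used median-ratio factors instead. PDGFC remained lower and past the threshold under every alternative run, with a log2 change from -1.66 to -1.32, and from -1.43 to -1.32 when a library was left out. Without a library, between 1524 and 1841 genes were higher and between 1653 and 2026 lower, and between 13 and 17 changed 2-fold. At an adjusted p under 0.01, 1038 genes were higher and 1122 lower, by construction. The 2-fold count, 12 in the main test, was 51 with a pseudocount of 0.1, 61 with 0.01 and 68 with limma-voom, whose fold changes are less compressed for low genes. It was 4 at a minimum RPKM of 5 and 3 at a minimum CPM of 5, where fewer genes were tested, and limma treat against 1.5-fold called 3 genes. Higher genes were 47.5% of the calls in the main test, 52% with median-ratio and 41.3% with upper-quartile scaling and 53.4% with limma-voom. In all, 0 genes called in the main test were called in the opposite direction under any setting.

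The replicate numbers did not pair the samples. Correlations of deviations between libraries of the same number were -0.101, -0.111 and -0.018. With the replicate number as a block, 1628 genes were higher, 1841 lower and 12 changed 2-fold, and the PDGFC change was -1.36. Under the block the mitochondrially encoded list passed (adjusted p = 0.023) and 10 named genes lost their call. Without the block that list did not pass with an estimated correlation (adjusted p = 0.65) or without shPDGFC replicate 2 (0.23, median 0.12).

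Among the leading lists, ERK output kept a positive median (0.30 to 0.52) and autophagy a positive median (0.16 to 0.20), both with an adjusted p under the threshold in every alternative run (at most 0.048). With an estimated correlation, ribosomal proteins (median -0.15, adjusted p = 0.50) and YAP targets (median 0.16, adjusted p = 0.075) no longer passed. With fry, which compares a list with no other genes, androgen-induced targets (median -0.046, adjusted p = 0.023) and androgen-repressed genes (median -0.08, adjusted p = 0.0015) passed. Fry called 11 lists that camera did not. Without a filter the ATF4 (adjusted p = 0.016) and glycolysis (0.015) lists passed, and at a minimum RPKM of 5 the glycolysis (0.049), neuroendocrine (0.049) and other prostate lines (0.029) lists did. The last also passed at a minimum CPM of 5 (0.029) and with limma-voom (0.032). At the filter of the main test none of these 4 passed with an estimated correlation (0.41 to 0.65). RAP1 components did not pass under any (adjusted p from 0.29 to 0.76). No list that passed turned the direction given by its test, and no named gene that passed turned its direction. Medians of lists called by fry alone could change sign. The epithelial median was 0.037 in the main test and -0.018 without shNC replicate 2. The neuroendocrine median was -0.0054 in the main test and 0.0058 with limma-voom. With a library left out, calls of named genes were lost in 51 fits, gained in 1 and unaltered in 728. Depth limits genes near 1 RPKM: about 25.4 reads for a gene of KLK3's length in the shallowest library.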

Other observations

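The tests on the androgen targets were chosen after the levels were seen, and all other tests here before their outcome was seen, although limma-voom and the GC and length corrections were added as alternatives after the main result was known.

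Some single genes were looked up beyond the comparison. In shNC, VIM was at 270.4 RPKM, KRT8 at 81.1 RPKM, NEFM at 52.97 RPKM and NEFL at 45.1 RPKM. LIN28B (25.9 RPKM), GATA2 (18.5 RPKM), HOXA9 (17.5 RPKM), HOXB13 (8.71 RPKM), CDX2 (8.54 RPKM), GATA4 (6.13 RPKM) and SOX2 (5.31 RPKM) were also measured there. GRHL2 had 2 reads over the 3 shNC libraries and 7 over the 3 shPDGFC libraries, and ESRP1 was at 0.109 and 0.182 RPKM. These genes were chosen after their values were seen, and no test was made of them as a group.

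The rise of the ERK output and feedback genes in shPDGFC was weighed first. With each library's GC trend removed the list's median log2 change was 0.38 (camera, adjusted p = 1.5e-08), and with its length trend removed 0.39 (adjusted p = 1.7e-08), against 0.39 in the main test, which argues against either trend as its whole source. With limma-voom on the recovered reads the median was 0.52. A pseudocount shrinks the changes of low genes, so a larger value there was to be foreseen and decides nothing. At a minimum RPKM of 5 the median was 0.32 (camera, adjusted p = 0.0076), and at a minimum CPM of 5 it was 0.41 (adjusted p = 2.0e-08). These values argue against low counts as the whole source of the rise. A hypothesis from the groups compared is that lower PDGFC may raise ERK output. Transcripts of the ERK cascade itself did not stand apart in a common direction (camera, adjusted p = 0.90). That list mixes activators with inhibitors: NF1, a negative regulator of RAS, fell, and PEBP1, an inhibitor of RAF, rose. A test for a common direction therefore cannot decide whether the cascade changed. A link between PDGFC and ERK output was not tested, and protein phosphorylation was not analysed here. Other effects of the hairpin, and culture differences between the 2 groups, were not tested and stay open.

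The near absence of KLK3, KLK2 and some other listed androgen targets, though not of most of the list, in all libraries was weighed second. A gene of KLK3's length at 1 RPKM would have 25.4 reads in the shallowest library, which argues against too few reads. Of the 34 listed targets outside the kallikreins, 7 also lay under 0.2 RPKM in every library. Reads shared between kallikreins cannot explain those 7, but the count does not decide whether KLK3 and KLK2 lost reads this way. One hypothesis is that the cells may be of another type than labelled, and HEK293 was examined because its list had been fixed beforehand. Of its 14 genes 11 reached 1 RPKM in every library, led by NEFM and NEFL. Of 10000 random lists of protein-coding genes 11.8% had as many (median 8). That count takes no account of how restricted a gene is to a cell type, so it cannot decide for or against HEK293. SOX2 is also in the neuroendocrine list, and how many of the 14 are expressed in LNCaP was not analysed here. Lost androgen signalling in prostate luminal cells is the other hypothesis, with HOXB13, FOXA1, KRT8 and KRT18 expressed. Whether HEK293 cells express these genes too was not analysed here. However, GRHL2 and ESRP1 were near absent in both groups, and in shNC CDH1 was at 1.37 RPKM and VIM at 270.4 RPKM. Whether loss of androgen signalling alone would lower such epithelial genes was not tested. Of 24 listed epithelial genes 12 were at 1 RPKM in every library, and 88.3% of random lists had as many (median 14). The same limit holds for this count. The genes and counts examined here do not tell the 2 hypotheses apart, and no reference profile was compared. Other genes that might separate them were not examined.

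The fall of ribosomal protein mRNAs was weighed last. With each library's length trend removed the list's median log2 change was -0.13 against -0.15 in the main test, which argues against the length trend as its whole source. The 64 tested ribosomal protein pseudogenes had a median log2 change of -0.02 (quartiles -0.18 and 0.078), with 3 higher and 6 lower, so whether reads moved between genes and pseudogenes cannot be told apart from a change of the mRNAs. Mean log2 levels of the 73 genes were 8.74, 8.64 and 8.74 in shNC and 8.54, 8.59 and 8.52 in shPDGFC, so the groups did not overlap, with 8.64 and 8.59 as the closest values. An effect of the knockdown stays open.

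For the counts of called genes, 3 libraries against 3 make 10 splits, too few for a share under 0.05. Of the 10 splits, 1 (the real one) gave as many higher genes, 2173, with 0 as the highest of the others. The same held for lower genes, 1 split with 2398 against 0, and for genes changed at least 2-fold, 1 split with 12 against 0.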
